A study of Mus musculus with 2 samples.

How the data were processed

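Kidney RNA from male CD-1 mice was compared on 2 dual-colour expression arrays. Per the labels, the mice were 7 weeks old at the start and ate a diet with 0.2% adenine by weight, alone or with 2% HMPA by weight, for 1 week. The sample titles instead give an age of 12 weeks and name 5 mice, without saying whether that number is per diet or whether their RNA was pooled. On array 1 the adenine sample carried Cy3 (green) and the HMPA sample Cy5 (red), and on array 2 the dyes were swapped. The labels name no separate animals or extracts per array, so the 2 arrays were treated as a technical dye swap of 1 RNA sample per condition. That leaves no residual degree of freedom among samples, and no p-value was computed for the main comparison. Both arrays came from 1 slide and 1 scan, and each array held both conditions.

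Per the labels, RNA was extracted with QIAzol and copied into dye-labelled cRNA from a T7 primer. Per the file headers, the authors scanned the arrays on an Agilent scanner and quantified them with Feature Extraction 12.2.0.7, while the submitters' notes name version 9.5. The signal and background columns hold intensity per the file headers: the mean of each spot's pixels and the median of its local background, without normalization. The deposited ratio column is the log10 of red over green after Feature Extraction's background subtraction and dye normalization. The deposited value table holds the same log10 ratio, not turned for the dye swap, within 0.00498 on array 1 and 0.00499 on array 2. The p-value column comes, per the file headers, from Feature Extraction's error model for 1 spot within 1 array, so it carries no information on animals.

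Each array had 45018 spots, of which 1639 were controls and 43379 measured genes. Feature Extraction marked 281 of these 43379 spots as unreliable on array 1 and 297 on array 2, and none was saturated. Signal over background sets the depth. On array 1, 60.9% of spots were well above background in green and 57.9% in red. On array 2 the shares were 61.2% in green and 67.9% in red. The 245 probes printed 10 times had a median SD between repeat spots of 0.10 (log2) on array 1 and 0.09 on array 2. The number of arrays limits the precision of every value.

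Processing used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Background was corrected by limma's normexp method with an offset of 50, control and unreliable spots got a weight of 0, and ratios were normalised by loess within each array. Ratios were turned to HMPA over adenine alone, and spots of 1 probe were averaged. A probe was kept if it was well above background in the same condition on both arrays, which left 25138 of 41174 probes and 16698 genes. Of these genes, 15237 were above background in all 4 channels. A gene was represented by its probe with the highest mean signal. Among 6031 genes with more than 1 kept probe, 559 had probes that disagreed in sign. Probe positions are those of the files, on mouse build mm9, and current gene names were taken from a RefSeq table through the accession of each probe. Of the kept probes, 21374 were named by accession, 1932 by symbol and 8 by an older symbol, and 1824 kept the name in the file.

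A gene was counted as higher or lower by a rule of size, not by a test: a mean ratio of at least 2-fold over the 2 arrays and at least 1.5-fold in the same direction on each. The same rule was applied to the dye contrast, in which the condition cancels, as a count of background. The value after ± is the distance of each array from their mean. For 36 gene lists (1079 genes, 972 measured), the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. Genes are not replicates, so this percentile is a description of these hybridisations and not a test. A gene dim in 1 condition was given as "at least" a fold, against its signal or the background floor. The rule, the lists, the alternatives and the choice of genes to name were set before the data were examined. Named genes were the 12 highest and 12 lowest that met the rule and were above background in all 4 channels. Genes whose name is only an accession or a clone were left out of these. To these were added up to 4 members per list that met the rule, with up to 2 given as values where none did. The set also held 26 genes of fibrosis, inflammation and tubular injury, chosen to match the themes of the study's title, and the 6 largest bounds. A few genes that these rules name are not reported here.

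The procedure was tested on simulated data of 40978 probes with known ratios. The rule found 10.4% of 67 probes changed 2-fold, 70.1% of 67 changed 4-fold and 90.9% of 66 changed 8-fold, and 0 of 24938 unchanged probes. Probes made 4-fold different measured 1.51 on the log2 scale, so ratios are compressed and small ones are missed. The simulation used the same noise level for all probes and changed few of them, all above background in all 4 channels. Its noise was not matched to the real arrays, whose distance from their mean was 0.11 at the median and 0.31 at the 90th percentile. These rates, and the 0 unchanged probes found, may therefore not hold for the real data. Among 200 random lists of 40 genes, 6% fell outside the central 95% of random medians, and 100% did after a shift of 0.5. Both kinds of list were random draws, so the first share follows from the method. It does not show how often lists of genes that vary together would fall outside.

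Alternatives covered the background correction, the offset, median centring in place of loess, scaling between arrays, Feature Extraction's own ratios, the deposited value table, the filter on dim probes and the mean over all probes of a gene. They also covered a looser and a stricter rule, the spot p-values, each array alone, unmatched random lists and limma with the arrays taken as separate replicates. Gene families sharing a symbol stem, with at least 20 measured members, were looked at only after the data had been seen, 56 in all. No array was left out, and no batch could be compared.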

Results

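The data were gene expression ratios in kidney from mice fed adenine, which leads to crystals in the tubules and is used as a model of chronic kidney disease. One condition was the adenine diet alone. The other was the same diet with HMPA, 3-(4-hydroxy-3-methoxyphenyl)propionic acid, a phenolic acid. The 2 conditions were hybridised together on each of 2 arrays with the dyes swapped, as 1 RNA sample per condition. The median spot signal on array 1 was 64.6 in green and 34.0 in red, over backgrounds of 25 and 22. On array 2 it was 56.7 in green and 51.4 in red, over backgrounds of 24.5 and 22. There was no replicate of animals in the ratios, so no p-value is given and differences between animals could not be assessed.

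The comparison of HMPA with adenine alone covers transcripts of fibrosis and inflammation in this model, not fibrosis itself. No kidney from mice on a diet without adenine was on the arrays. The ratios therefore do not show which genes adenine changed, or whether HMPA brought any gene back toward its normal level. With HMPA, genes of matrix, inflammation, macrophages and tubular injury were lower, and genes of the proximal tubule, fatty acid oxidation and xenobiotic metabolism were higher. Of 56 measured fibrosis and matrix genes, 48 met the rule as lower and 0 as higher. Of 68 proximal tubule genes, 63 met it as higher and 0 as lower. The highest named gene was Slc7a13, an amino acid transporter of the proximal tubule, 32.7-fold higher (log2 ratio 5.03 ± 0.0026). The lowest named gene was Cfd, complement factor D, which fat cells also make in quantity, 28.6-fold lower (−4.84 ± 0.012).

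Among 16698 measured genes, 1109 (6.64%) met the rule as higher with HMPA and 1289 (7.72%) as lower. The dye contrast gave 0 genes. Differences of at least 4-fold were found for 256 higher and 225 lower genes, and of at least 8-fold for 46 and 27. Log2 ratios correlated between the arrays with r = 0.889 across genes, which are not independent replicates, and the median distance of an array from the mean was 0.11. The balance of directions depended on the scaling: higher genes made up 46.2% of those that met the rule, and 27.5% (749 against 1973) with median centring in place of loess. That scaling moved the median of all genes from −0.04 to −0.22. With Feature Extraction's own ratios, 2043 genes were higher and 2461 lower, among them 1108 and 1239 of the genes above.

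**Figure D1:**
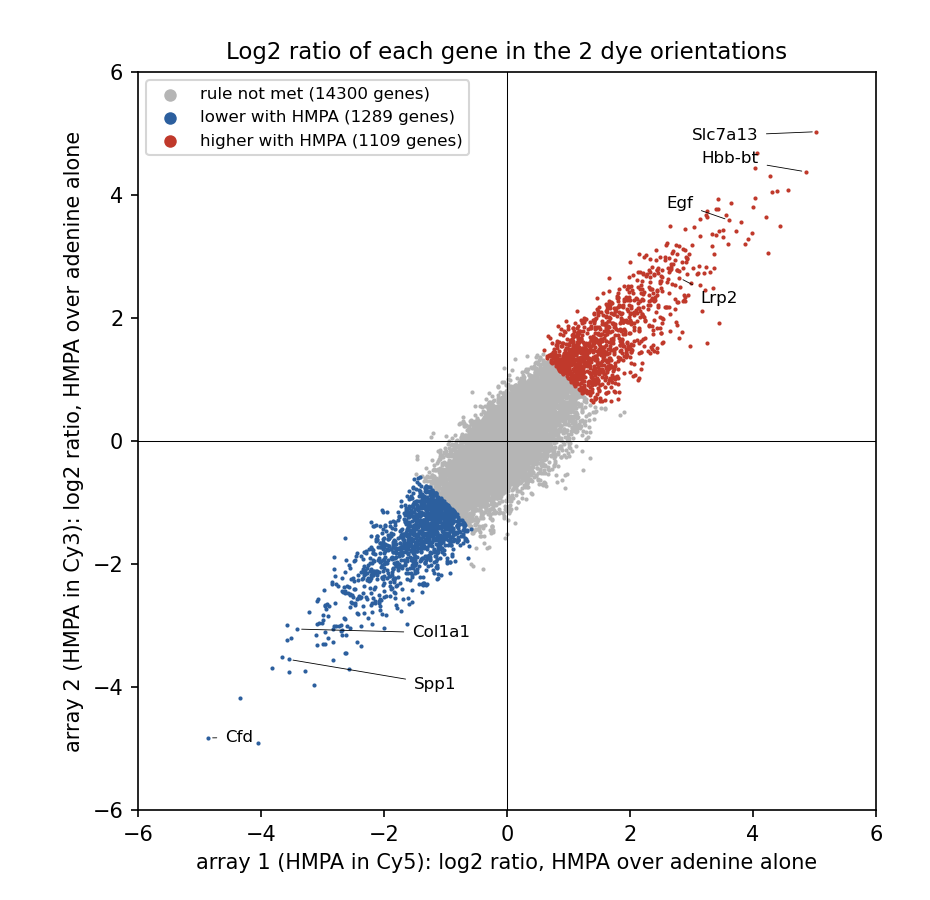
Each point is 1 of 16698 genes, with its log2 ratio of HMPA over adenine alone on array 1 (horizontal) and on array 2 with the dyes swapped (vertical). The 1109 genes that met the rule as higher are red, the 1289 lower are blue and the 14300 others are grey.

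The Slc7a13 probe lies on chromosome 4 from 19768758 to 19768817 and the Cfd probe on chromosome 10 from 79355302 to 79355361 (build mm9). No annotation on that build was used here, so exon or UTR is not assigned. After Slc7a13, the highest named genes were Hbb-bt, a beta globin (4.62 ± 0.24), and Acsm3, an acyl-CoA synthetase (4.38 ± 0.31). The carboxylesterases Ces2b (4.33 ± 0.25) and Ces2c (4.30 ± 0.016) followed. Akr1c14, Pzp, Slc22a28, Dnase1, Slc6a19, Ces1f and Kap (3.90 ± 0.11) completed the 12 highest, in falling order. Slc6a19 carries neutral amino acids, and Kap encodes the androgen-regulated protein of the proximal tubule. After Cfd, the lowest named genes were Zbtb8b (−4.48 ± 0.44, from a predicted transcript, with a second probe at −0.10) and Hp, encoding haptoglobin (−3.65 ± 0.11). Next were Spink12 (−3.59 ± 0.08) and Spp1, encoding osteopontin (−3.55 ± 0.0036). Mgp, an inhibitor of calcification, complement C3, Timp1, Lgi2, Col1a1, Trem2 and Gpc3 completed the 12 lowest, each at least 9.14-fold lower. With the mean over all probes of a gene, Hbb-bt was 3.97, Ces2b 3.66, Ces2c 3.59, Zbtb8b −2.29 and Trem2 −2.38, and with Feature Extraction's ratios Pzp was 5.01 and Spink12 −4.24. Probes for globins, for Ces1 and Ces2 members and for Slc22a28 may bind transcripts of close paralogs, so their values can be shared among these genes.

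Of the 26 genes chosen to match the themes of the study's title, 21 met the rule as lower and 1 as higher. All 26 are also members of the gene lists below, so this count is not separate from the list results. The collagens Col1a1 (−3.23 ± 0.17; chromosome 11 from 94813075 to 94813134), Col1a2 (−2.89 ± 0.27) and Col3a1 (−2.82 ± 0.14) were lower, as was Col4a1 of the basement membrane (−1.87 ± 0.13). Timp1, an inhibitor of matrix proteases, was −3.35 ± 0.15 and Ccn2 −3.13 ± 0.57. Vim was −2.28 ± 0.05, Fn1 −1.86 ± 0.04, Acta2, smooth muscle actin, −1.56 ± 0.08 and Tgfb1 −1.14 ± 0.03. Of the inflammatory genes, Vcam1 (−2.92 ± 0.24), Il1b (−2.58 ± 0.04), Ccl2 (−2.03 ± 0.19) and Icam1 (−1.34 ± 0.0054) were lower. The macrophage genes Adgre1 (−2.04 ± 0.15) and Cd68 (−1.64 ± 0.27) and the leukocyte gene Ptprc (−1.24 ± 0.17) were lower too. Il6 was at least 2.51-fold lower, since it was not above background with HMPA. Ccl5 (−0.91 ± 0.24), Tnf (−0.45 ± 0.08), Nlrp3 (0.04 ± 0.02) and Cxcl10 (−0.32 ± 0.49, with opposite signs on the arrays) did not meet the rule. The injury genes parted: Spp1 and Lcn2 (−2.98 ± 0.03) were lower, while Havcr1, encoding KIM-1, was 2.10-fold higher (1.07 ± 0.04). With median centring Havcr1 was 0.76 and no longer met the rule. Values are those of the brightest probe, and the other Havcr1 probe was 1.32. Other probes of the lower genes lay nearer 0, up to −0.25 for Col1a1, −0.22 for Col4a1, −0.16 for Fn1 and −0.08 for Acta2. With the mean over all probes of a gene, Fn1 (−0.95), Acta2 (−0.99), Icam1 (−0.94) and Ptprc (−0.54) no longer met it, and Col1a1 (−1.86), Col3a1 (−1.76), Col4a1 (−1.19) and Vcam1 (−2.15) lay nearer 0. Tnf met the rule with Feature Extraction's ratios (−1.87), and Ccl5 with median centring (−1.17) and on array 1 alone (−1.15). Of the 151 genes named by the rules, 25 moved by over 1.5-fold with Feature Extraction's ratios and 19 with the mean over all probes.

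Gene lists outside the central 95% of random lists numbered 24 of 36, 15 below and 9 above. The fibrosis and extracellular matrix list had a median log2 ratio of −1.82 (−1.72 on array 1 and −1.87 on array 2), below all 10000 random lists, and Col8a1 was among its lowest members (−3.12 ± 0.17). In the list of inflammatory cytokines and signalling, 41 of 59 genes were lower and 2 higher, with a median of −1.41 (−1.34 and −1.55). Its lowest members were the chemokines Ccl6 (−3.01 ± 0.05) and Ccl12 (−2.88 ± 0.19), with Vcam1 and the signalling inhibitor Socs3 (−2.83 ± 0.11). In the tubular injury list, 29 of 38 genes were lower and 1, Havcr1, higher, with a median of −1.45 and low values for Krt20 (−2.89 ± 0.20) and Mmp7 (−2.85 ± 0.48). Both lists lay below all random lists. Another list held 3 of the fibrosis genes, 1 of the inflammatory genes and 10 of the injury genes. Of the immediate early genes, 14 of 24 were lower and 0 higher (median −1.28, below all random lists). Examples are the transcription factors Egr2 (−3.13 ± 0.03), Egr1 (−2.56 ± 0.31), Klf6 (−2.38 ± 0.25) and Junb (−2.30 ± 0.68). Socs3 was −1.55 with the mean over all probes, and Mmp7 was −3.60 with Feature Extraction's ratios.

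Among the immune cell lists, the myeloid ones had the lowest medians. Of 44 macrophage and dendritic cell genes, 37 were lower and 0 higher (median −1.94, below all random lists), with Trem2 (−3.20 ± 0.11), the protease Ctss (−3.04 ± 0.41), Clec4d (−3.03 ± 0.41) and Apoe (−2.94 ± 0.12) lowest. Of 22 neutrophil genes, 10 were lower and 2 higher (median −0.87, below all random lists, −1.52 with the smaller offset and −2.75 with Feature Extraction's ratios, with 4 values that are bounds). The calprotectin genes S100a9 (−3.40 ± 0.17) and S100a8 (−2.55 ± 0.24) were lower, while Hdc, which makes histamine, was higher (2.88 ± 0.03). With Feature Extraction's ratios Clec4d was −4.64 and S100a8 −3.43. Of 29 T and NK cell genes, 1 was lower (Il7r, −1.40 ± 0.37, and −2.66 with Feature Extraction's ratios) and 1 higher. Their median of −0.17, at the 1.81 percentile of random lists, was −0.40 with median centring (0.44 percentile), −0.50 with Feature Extraction's ratios (1.70 percentile) and −0.09 without the filter on dim probes (2.16 percentile). It was inside the central range with the smaller offset (5.78), without background correction (4.59), with the mean over all probes (2.81), on array 2 alone (5.01) and against random lists not matched on signal (7.75). Of 17 B and plasma cell genes, 1 was lower (Blnk, −1.12 ± 0.08), with a median of −0.38 (−0.16 without the filter on dim probes, −0.66 with Feature Extraction's ratios).

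Complement and coagulation genes were lower in 14 of 30 cases and higher in 1 (median −0.92, below all random lists, and −1.51 with Feature Extraction's ratios). Beside Cfd, C3 was −3.51 ± 0.23 and the protease inhibitor Serpine2 −2.53 ± 0.02. With the mean over all probes these were −2.08 and −1.48, and with Feature Extraction's ratios Serpine2 was −3.19. Of 18 antigen presentation genes, 6 were lower and 0 higher (median −0.88). The class II genes H2-Eb1 (−1.79 ± 0.27), Cd74 (−1.77 ± 0.17) and H2-Ab1 (−1.64 ± 0.13) and the class I gene H2-K1 (−1.34 ± 0.02, and −0.88 with the mean over all probes, short of the rule) were among the lower. Interferon response genes went both ways by the rule, with 4 of 39 higher and 3 lower. Their median of −0.39 (−0.69 with median centring) was at the 0.14 percentile of random lists, and 27 ratios were below 0 and 12 above. The GTPases Igtp (2.22 ± 0.25), Gbp6 (1.48 ± 0.06, and 2.31 with Feature Extraction's ratios) and Irgm2 (1.21 ± 0.17, not meeting the rule with median centring) were higher, and Ifi27l2a was lower (−1.38 ± 0.49, and −0.89 on array 1 alone, short of the rule). Of 15 genes of NADPH oxidase and oxidant production, 5 were lower and 2 higher (median −0.78). The phagocyte oxidase genes Ncf4 (−2.20 ± 0.27), Cybb (−2.0 ± 0.17) and Rac2 (−1.69 ± 0.56) were lower, and Duox1 was higher (1.31 ± 0.17). Cybb was −1.34 with the mean over all probes, and Duox1 was 2.0 with the smaller offset and 3.17 with Feature Extraction's ratios.

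Medians of all 3 tubule segment lists were above 0. The proximal tubule list had a median of 2.15 (2.19 on array 1 and 2.01 on array 2), above all random lists, and another list held 6 of its genes. Slc7a13, Acsm3, Slc22a28 (4.19 ± 0.13) and Slc6a19 (3.97 ± 0.48) were its highest members. Of 32 genes of the loop of Henle and distal tubule, 9 were higher and 0 lower (median 0.48, 0.22 with median centring and 0.76 with Feature Extraction's ratios). Egf (3.60 ± 0.0098), the calcium-binding Pvalb (3.00 ± 0.13) and S100g (1.96 ± 0.12), and Kl, encoding klotho (2.32 ± 0.19), were highest. With Feature Extraction's ratios Pvalb was 4.20, and with the mean over all probes Kl was 1.66. Of 33 collecting duct genes, 11 were higher and 2 lower (median 0.41, 0.17 with median centring and 0.94 with Feature Extraction's ratios). The anion exchangers Slc4a1 (2.61 ± 0.17) and Slc26a4 (2.42 ± 0.05), the water channel Aqp3 (2.59 ± 0.30) and the ammonium transporter Rhbg (2.51 ± 0.26) were among the higher, and Slc4a1 was 3.54 with Feature Extraction's ratios. Both lists lay above all random lists. Podocyte genes were lower in 4 of 20 cases and higher in 0, with a median of −0.32 at the 2.54 percentile, inside the central range. It was −0.57 (0.55 percentile) with Feature Extraction's ratios, −0.50 (0.69 percentile) with the smaller offset, −0.44 (1.09 percentile) without background correction and −0.54 (4.43 percentile) with median centring, and at the 1.55 percentile against unmatched random lists. Examples are Kirrel (−1.43 ± 0.17), Tcf21 (−1.10 ± 0.15) and Synpo (−1.04 ± 0.10, uncertain since another probe gave 0.06). Tcf21 on array 2 alone (−0.96), and Synpo on array 1 alone (−0.94) and with the mean over all probes (−0.49), fell short of the rule. Of 26 endothelial genes, 1 was lower, Pi16 (−1.53 ± 0.05), with a median of −0.16 inside the central range (−0.26 on array 1 alone, −0.40 with median centring and −0.26 with Feature Extraction's ratios).

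**Figure D2:**
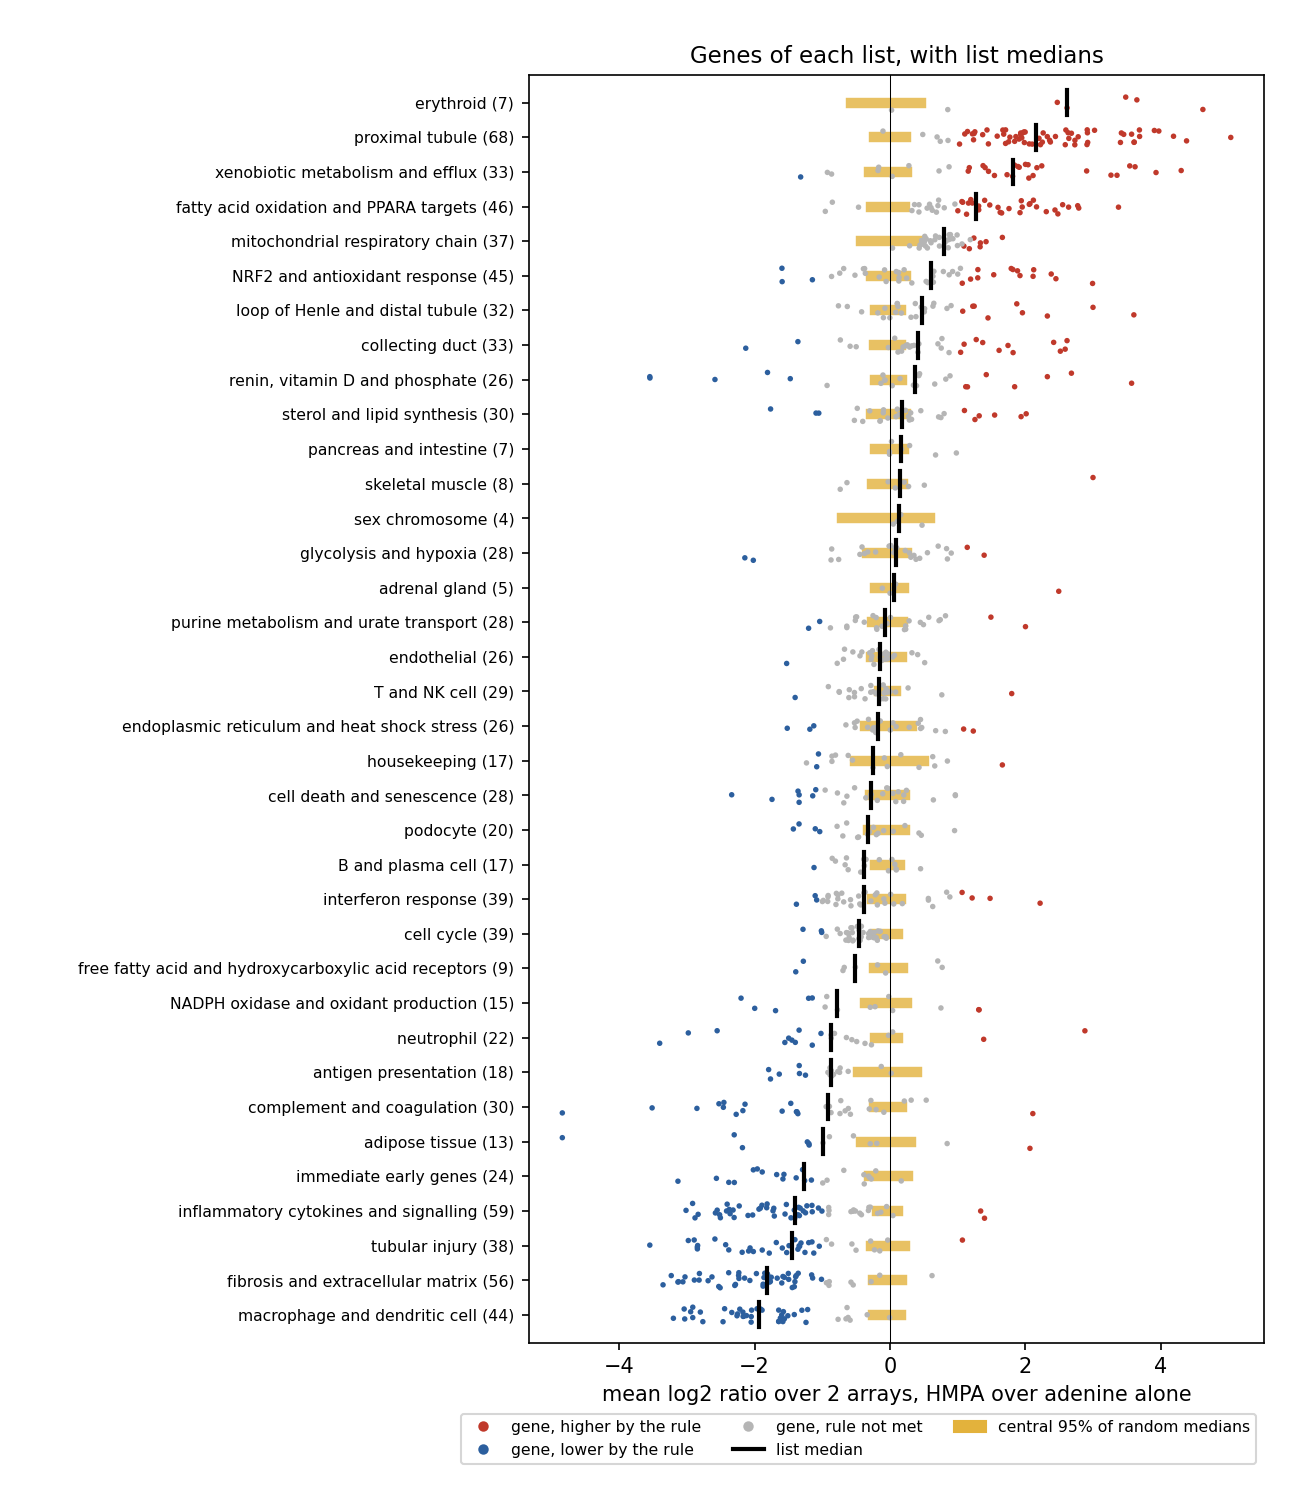
Each dot is a measured gene of the list named at the left, with the number of measured genes in brackets, placed at its mean log2 ratio of HMPA over adenine alone. Black lines are list medians, from −1.94 for macrophage and dendritic cell genes to 2.61 for erythroid genes, and yellow bars span the central 95% of random list medians.

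Of 46 genes of fatty acid oxidation and PPARA targets, 30 were higher and 0 lower (median 1.26, above all random lists). Cyp4a12a (3.37 ± 0.03), Ehhadh (2.79 ± 0.02), Vnn1 (2.77 ± 0.0095) and the peroxisomal oxidase Acox2 (2.64 ± 0.18) were highest. Of 37 mitochondrial respiratory chain genes, 7 were higher and 0 lower (median 0.80, above all random lists). Sdha (1.66 ± 0.04) and Sdhb (1.33 ± 0.37) of complex II, Ndufs1 of complex I (1.42 ± 0.37) and Cyc1 (1.33 ± 0.11) were among them. Sdha with the mean over all probes (0.999) and Sdhb on array 2 alone (0.96) fell short of the rule. Of 33 genes of xenobiotic metabolism and efflux, 24 were higher and 1 lower (median 1.81, above all random lists). Cyp2a5 (3.62 ± 0.06) and Cyp2a4 (3.54 ± 0.34) are close paralogs, and their probes may not tell them apart. Ces2c and Ces1f (3.93 ± 0.28) were the other highest members. Of 45 NRF2 and antioxidant genes, 14 were higher and 3 lower. Their median of 0.61 lay above all random lists, and was 0.56 on array 1 and 0.39 on array 2, where 3 and 24 random lists lay at or above it. Ces1g (2.99 ± 0.14), catalase (Cat, 2.45 ± 0.45), the glutathione transferase Gsta3 (2.38 ± 0.33) and malic enzyme (Me1, 2.12 ± 0.17) were highest, and Ces1g was 3.63 with the smaller offset and 4.35 with Feature Extraction's ratios. Of 30 genes of sterol and lipid synthesis, 6 were higher and 3 lower (median 0.18, inside the central range, −0.10 with median centring, 0.28 with Feature Extraction's ratios, and at the 98.3 percentile with the mean over all probes and the 98.7 percentile against unmatched random lists). Cyp51 (2.01 ± 0.19) and Nsdhl (1.54 ± 0.04) of the cholesterol pathway and Acss2 (1.94 ± 0.17) were higher, and the cholesterol exporter Abcg1 was lower (−1.76 ± 0.45).

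Glycolysis and hypoxia genes went both ways, with 2 of 28 higher, 2 lower and a median of 0.08 inside the central range (−0.22 with median centring, 0.20 with Feature Extraction's ratios and 0.03 on array 1 alone). Hexokinase 2 (Hk2, −2.02 ± 0.08) and the lactate exporter Slc16a3 (−2.14 ± 0.26) were lower. Bnip3 (1.39 ± 0.05) and Adm (1.14 ± 0.18, not meeting the rule with median centring or on array 2 alone) were higher. Of 28 genes of purine metabolism and urate transport, 2 were higher and 2 lower (median −0.08, inside the central range, −0.24 with median centring and −0.02 with genes above background in all 4 channels). The urate exporter Abcg2 (2.00 ± 0.07) and adenosine kinase (Adk, 1.49 ± 0.30) were higher, and Xdh (−1.20 ± 0.15) and Ada (−1.04 ± 0.18) were lower. Xdh with the mean over all probes (−0.72) and Ada on array 1 alone (−0.86) fell short of the rule. Of 26 genes of renin, vitamin D and phosphate, 7 were higher and 5 lower, with a median of 0.37 at the 99.95 percentile (0.15 with median centring, 0.15 without the filter on dim probes and 0.81 with Feature Extraction's ratios). The phosphate transporters Slc34a3 (3.57 ± 0.16) and Slc34a1 (2.68 ± 0.77) were higher and Mgp (−3.55 ± 0.41) lower, and another list held 7 of these genes. The list of free fatty acid and hydroxycarboxylic acid receptors was mixed, so its median is not that of such receptors alone. It also named the bile acid receptor Gpbar1, the aryl hydrocarbon receptor Ahr, and Ahrr, Tiparp, Cyp1a1 and Cyp1b1. Of its 9 measured genes, 2 were lower and 0 higher, Hcar2 (−1.28 ± 0.07) and Cyp1b1 (−1.39 ± 0.55). Their median of −0.51, at the 0.05 percentile, was −1.02 with Feature Extraction's ratios (0.65 percentile) and −0.07 without the filter on dim probes (9.86 percentile), and 4 of the 9 values are bounds. Hcar2 was −1.90 with the smaller offset and −3.0 with Feature Extraction's ratios, and Cyp1b1 fell short of the rule on array 1 alone (−0.84).

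Of 39 cell cycle genes, 3 were lower and 0 higher (median −0.46, at the 0.02 percentile, and −0.75 with median centring). They were Mcm3 (−1.29 ± 0.24), Birc5 (−1.01 ± 0.11) and Mki67 (−1.01 ± 0.21). Each fell short of the rule under an alternative: Mcm3 (−0.82) and Mki67 (−0.79) with the mean over all probes, Mki67 also on array 2 alone (−0.80), and Birc5 on array 1 alone (−0.91). Of 28 genes of cell death and senescence, 7 were lower and 0 higher, with a median of −0.28 at the 3.17 percentile, outside the central range with median centring (−0.61, at 1.65), with the mean over all probes (0.85), on array 2 alone (1.49), on array 1 alone (1.07) and against unmatched random lists (1.06). The cell cycle inhibitors Cdkn2b (−2.34 ± 0.07) and Cdkn1a (−1.34 ± 0.16) were lower, as were Bbc3 (−1.74 ± 0.02) and Bak1 (−1.36 ± 0.10, uncertain since another probe gave 0.34, and −0.51 with the mean over all probes, short of the rule). Of 26 genes of endoplasmic reticulum and heat shock stress, 3 were lower and 2 higher. Their median of −0.18 was inside the central range, and was −0.04 on array 1 alone, −0.11 on array 2 alone, −0.03 with the mean over all probes and −0.32 with median centring. The small heat shock genes Hspb1 (−1.52 ± 0.01), Hspb8 (−1.18 ± 0.10) and Cryab (−1.13 ± 0.03, and −0.86 with the mean over all probes, short of the rule) were lower, and Hsph1 was higher (1.23 ± 0.13). Of 17 housekeeping genes, 1 was higher (Sdha, not with the mean over all probes) and 2 lower, Actb (−1.06 ± 0.05) and Rplp0 (−1.08 ± 0.36). The only kept Actb probe was dim, with a mean log2 signal of 7.75, against 15.5 for Rplp0. The list median of −0.25 was inside the central range (−0.11 on array 1 alone and −0.39 with median centring). Rplp0 fell short of the rule with median centring (−0.95), the smaller offset (−0.98), Feature Extraction's ratios (−0.72), the mean over all probes (−0.92) and array 1 alone (−0.72).

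Some markers of other tissues differed beside these groups. Of 7 erythroid genes, 5 were higher and 0 lower (median 2.61, above all random lists, and 0.85 without the filter on dim probes). Beside Hbb-bt, Hba-a1 was 3.64 ± 0.59 and Hba-a2 3.48 ± 0.04, and Slc4a1 is also in the collecting duct list. Of 13 adipose tissue genes, 6 were lower and 1 higher (median −0.99, at the 0.01 percentile, and −1.58 with Feature Extraction's ratios). Cidec of the fat droplet (−2.30 ± 0.06) and adiponectin (Adipoq, −2.18 ± 0.06) were lower with Cfd, and Cd36, also in the fatty acid oxidation list, was higher (2.07 ± 0.25). With Feature Extraction's ratios Cidec was −3.08 and Adipoq −3.16. Of 5 adrenal gland genes, 1 was higher, Hsd3b1 (2.49 ± 0.17, and 3.59 with Feature Extraction's ratios), with a list median of 0.06 (−0.0079 on array 1 alone, 0.02 on array 2 alone and 0.37 with Feature Extraction's ratios). Of 8 skeletal muscle genes, 1 was higher, Pvalb, which the distal tubule list also holds (list median 0.14, −0.03 without the filter on dim probes, 0.05 with median centring and 0.58 with Feature Extraction's ratios). None of 7 pancreas and intestine genes met the rule (median 0.17, −0.03 with median centring and 0.36 with Feature Extraction's ratios). Among them, Vil1 was 0.98 ± 0.16, and Pnliprp1, not above background with adenine alone, was at least 1.53-fold higher. Vil1 met the rule without background correction (1.01), with the smaller offset (1.03), Feature Extraction's ratios (1.08) and the mean over all probes (1.01), and on array 2 alone (1.14), and Pnliprp1 met it in the first 3 of these. None of 4 sex chromosome genes met it either (median 0.13, −0.11 with median centring, 0.31 on array 1 alone and 0.02 on array 2 alone), with Kdm5d at 0.47 ± 0.08 and Uty at 0.16 ± 0.06. These last 4 lists lay inside the central range, except that skeletal muscle was at the 97.69 percentile with genes above background in all 4 channels. Genes above background in 1 condition alone gave bounds: Stfa2l1 was at least 2.64-fold lower, Olr1 2.46-fold, Cstdc5 2.25-fold and Cstdc4 2.17-fold, and Nap1l5 was at least 2.34-fold higher. Their ratios were larger with Feature Extraction's ratios, from −4.67 for Stfa2l1 to 4.82 for Nap1l5.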

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

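No test in this part was chosen after the result was seen. Control probes enter no comparison, and those above the negative controls are given as values. Of 92 positive control probes, 14 were above the 99th percentile of the negative-control spots in a condition on both arrays, and 6 of these differed 1.5-fold or more the same way on both. The log2 ratio of HMPA over adenine alone was −0.71 for E1A_r60_a107, 1 of 10 probes of that control series and the 1 of them above the negatives. It was −1.80 for AT_ssM_AB_3, −1.32 for AT_ssM_AB_5, −1.21 for AT_ssM_RR_5, 0.86 for AT_ssM_GD_5 and 2.29 for AT_ssM_PC_3. What the AT_ssM probes target is not given in the sources used here, and no explanation was tested.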

How the results depend on the processing

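All alternatives were planned. None turned a gene that met the rule to the other direction. List medians changed sign for 4 lists with median centring, 1 without the filter on dim probes and 1 on array 1 alone, all inside the central 95%. Relative to all genes, those 4 medians with median centring were 0.12 for sterol and lipid synthesis and 0.19 for pancreas and intestine. They were 0.11 for sex chromosome and −0.004 for glycolysis and hypoxia. With median centring, 1973 genes were lower (749 higher). Feature Extraction's ratios gave 2043 higher and 2461 lower genes, with the deposited values these were 2040 and 2459, and the dye contrast gave 6 genes in each. The looser rule gave 2255 and 2699 genes, the 3-fold rule 471 and 480, by their thresholds alone. limma with the arrays as separate replicates gave 2503 and 3072 at an adjusted p under 0.05 with 1 residual degree of freedom, but the labels do not show that the arrays are separate animals. Other settings gave 997 to 1396 higher and 1018 to 1659 lower genes. Scaling between arrays changed no ratio, so it tests nothing. The fibrosis median was −1.93 without background correction, −2.03 with the smaller offset, −2.11 with median centring (−1.89 relative to all genes), −2.17 with Feature Extraction's ratios and −2.17 with the value table, and −1.55 with the mean over probes. The inflammatory median was −1.58 with the smaller offset, −1.69 with median centring (−1.47 relative to all genes), −1.87 with Feature Extraction's ratios and −1.87 with the value table. The proximal tubule median was 2.00 with median centring (2.22 relative to all genes), 2.28 with the value table, and 2.01 to 2.19 leaving out 1 array at a time. The cause of these moves was not tested. Lists outside the central 95% numbered 23 to 26, and 17 to 22 title genes were lower. Of 143 named genes that met the rule, 129 (mean over probes) to 143 met it under the settings tried, but their sizes moved: of 151 named genes, 77 moved beyond their spread with Feature Extraction's ratios (74 away from 0, by up to 3.54) and 33 with the mean over probes (32 toward 0, by up to 2.19). Low signal limits all this: 573 genes were above background with adenine alone only and 74 with HMPA only, and their ratios are bounds.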

Other observations

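The gene families and the last test on Cfd were chosen only after the result was seen. The other tests below address patterns seen in these same data, with predictions written before each test. The adipose and erythroid markers come from the gene lists above, so their tests are not independent of the list results. The tests on dye bias and on proximal tubule RNA reuse medians of those lists. They restate the pattern in another form and are no independent evidence. Among 56 families sharing a symbol stem, 5 lay below and 12 above the central 95% of random lists. A large family can lie outside on a small shift. The 127 olfactory receptor genes (Olfr) were dim, with a median log2 signal of 6.15, and 2 were higher and 1 lower. Their median of 0.05 was at the 100 percentile, as was that of 187 Tmem genes (0.15). Both families of the cytosolic ribosome had medians below 0, though many members did not meet the rule. Of 35 Rps genes, 20 met it as lower, 0 as higher and 15 neither way. Their median log2 ratio was −1.13 (−0.91 on array 1, −1.29 on array 2 and −0.86 with Feature Extraction's ratios). Of 47 Rpl genes, 15 were lower, 0 higher and 32 neither, with a median of −0.88 (−0.67 with Feature Extraction's ratios). Their probes were bright, with a median log2 signal of 14.3 for Rps and 13.8 for Rpl. Genes of the mitochondrial ribosome differed in sign from these, with medians of 0.39 for 29 Mrps and 0.44 for 49 Mrpl genes, none of which met the rule (0.16 and 0.24 with median centring).

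Of 306 solute carriers (Slc), 84 were higher and 18 lower, with a median of 0.47 (0.18 with median centring and 0.73 with Feature Extraction's ratios). Of 54 cytochrome P450 genes (Cyp), 22 were higher and 1 lower (median 0.44, and 1.92 with Feature Extraction's ratios), and of 20 aldehyde dehydrogenases (Aldh), 9 were higher and 1 lower (median 0.67). Of 38 collagens (Col), 19 were lower and 1 higher (median −1.0), and of 21 C-type lectin genes (Clec), 10 were lower and 1 higher (median −0.84).

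The 3 tubule lists were higher with HMPA while the matrix and macrophage lists were lower. Dye bias is argued against as the whole cause, since the medians of the proximal tubule, fibrosis and macrophage lists differed between the dye orientations by at most 0.32 and kept their signs. A larger share of proximal tubule RNA alone is also argued against in these hybridisations. The distal tubule median exceeded the macrophage median by 2.41, where that explanation needs both to be lower alike. The 95% bootstrap interval over genes was 1.92 to 2.79. Genes are not replicates, so it describes the spread among the listed genes and not among animals. Other differences in cell content stay open and were not tested, those of myeloid cells, of matrix-forming cells and of the tubule as a whole among them. A difference within tubule cells, and a difference between the animals sampled that does not come from the diet, also stay open and were not tested.

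Globin transcripts were higher with HMPA, at mean log2 signals of 13.0 for Hbb-bt and 12.7 for Hba-a1. Blood cell RNA in the kidney sample is a candidate explanation: the median of the 4 other erythroid genes measured was 1.66. One of them, Slc4a1, is also expressed in the collecting duct, and the median was 0.85 without it. Alas2 (2.47) was higher by the rule, while Klf1 (0.85) and Epb42 (0.02) were not. More blood left in the organ and more reticulocytes in the blood were not told apart by any test here.

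Cfd was lower with HMPA. Adipose tissue in the adenine sample is a candidate source: the 6 measured adipose markers, none in another list and 5 of them above background in all 4 channels, had a median of −1.21. They were picked from the adipose list, which includes Cfd. Of its 13 measured genes, 6 were lower and 1, Cd36, higher. Whether adipose tissue is the whole of the Cfd difference stays open. Cfd was lower than the lowest marker, Cidec, by a log2 difference of −2.54, and lower than Adipoq, the lowest with Feature Extraction's ratios, by −1.92 there. These markers were dimmer (mean log2 signal 8.05 for Cidec and 7.79 for Adipoq, against 10.6 for Cfd), which holds back their ratios, so the gap excludes nothing. Expression of Cfd in kidney cells themselves was not tested.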
